A study of Mus musculus with 6 samples.

How the data were processed

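Messenger RNA was sequenced from mouse naive CD4+ T cells stimulated for 6 h with antibodies to CD3 and CD28, in 3 samples with recombinant CCL19 and 3 without. Reads were aligned with STAR 2.5 to mm10 and counted per gene with featureCounts 1.5.0-p1 of the Subread package, per the submitters' processing notes. Libraries were made with an Illumina TruSeq kit, per the labels. The deposited table holds raw read counts per gene, whole numbers with no normalization, with NCBI Gene IDs, symbols and mm10 coordinates, per the file headers. Strand setting, handling of reads with several matches and annotation release are not given in the sources used here. The authors also deposited a list of changed genes with the direction in words. DESeq2 1.28.1 is among their tools per the submitters' processing notes, and the threshold behind the list is not given in the sources used here.

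Groups and replicate numbers came from the sample titles and treatments. The labels name no batch. The 6 libraries held between 16978736 and 27429898 counts. Of 24470 genes listed, 15905 had a count in any library and 11666 passed edgeR's filterByExpr. TMM factors lay between 0.9792 and 1.016, and the biological coefficient of variation was 8.72%. Pearson's r of log2 CPM between libraries lay between 0.984 and 0.9935. The lowest chi-square per degree of freedom between any pair of libraries was 5.32, between CCL19 replicate 3 and no-CCL19 replicate 3, so no library was a copy or a resampling of another.

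The 3 CCL19 libraries were compared with the 3 no-CCL19 libraries with edgeR 4.0.16 (quasi-likelihood F test, TMM) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. DESeq2 1.42.0 (Wald test, own size factors, independent filtering at 0.1) gave an adjusted p to 9613 genes, and limma 3.58.1 (voom, TMM) was also run. Log2 fold changes and their SE come from the edgeR fit unless DESeq2 is named, and CPM values are scaled by TMM. Log2 CPM used a prior count of 2. Shares of counts and list scores of single libraries were compared with an exact permutation test, 2-sided, whose smallest p for 3 against 3 is 0.1. The leading component came from log2 CPM of all tested genes.

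Before the data were examined, 44 gene lists were fixed from general knowledge, and 42 had at least 5 tested members. They cover T cell activation, quiescence, CCR7 signalling, cytokines, helper subsets, interferon responses, growth, metabolism, stress, cell cycle and markers of other cell types. Lists share members, such as Myc, Il2 and Hspd1. They were tested with camera from limma at a preset correlation of 0.01 between genes, adjusted over lists. camera with an estimated correlation and fry were alternatives. Each list was also counted by edgeR, adjusted over all genes and adjusted over the list alone, and by DESeq2.

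The rule for named genes was also fixed before the data were examined. It takes genes chosen by name, among them Ccr7, Cd69, Il2ra, Il2, Cd4 and Myc. It adds the genes past the threshold with the largest changes or, if none passes, the 10 with the smallest p in each direction. Genes so added must have a mean log2 CPM of at least 1 and groups that do not overlap. Genes with a predicted-gene or clone name are left out. It also adds up to 4 called members of each list that passes. As edgeR called no gene, called members were read as those called by DESeq2 and the lists as those passing camera, a reading chosen after the edgeR result was seen. This names 66 genes, of which DESeq2 called 44 higher and 20 lower. Other genes that the text names, among them markers of other cell types and mitochondrial genes, lie outside this rule and were chosen after their values were seen.

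GC content and length of transcripts came from the GENCODE annotation of the same assembly and were available for 11188 tested genes (95.9%). A per-library offset was fitted with natural splines of 5 degrees of freedom each. The other alternatives were DESeq2 size factors, no filter, a filter of 1 CPM in at least 3 libraries, a robust prior, a 1.5-fold minimum, a threshold of 0.01, a replicate block, each library left out, thinning to the smallest total, and shares without the 10 highest genes.

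The tests were tried on simulated counts for the CCL19 comparison, 11637 genes with 200 drawn as changed. Simulated genes varied independently of each other, unlike genes in real libraries. The shares recovered and false therefore need not hold for the real counts. edgeR recovered 26.9% of genes changed by 1.3-fold, 62.7% at 1.5-fold and 84.4% at 2-fold, with 4.2% of its calls false. DESeq2 recovered 28.4%, 62.7% and 84.4% with 7.26% false, and limma 26.9%, 62.7% and 84.4% with 2.56% false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Genes for the constant parts of antigen receptors were not analysed because none was found by symbol in the table.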

Results

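RNA was sequenced from naive CD4+ T cells, the helper T cells that have not yet met antigen, which were purified with magnetic beads from the spleen and skin-draining lymph nodes of male C57BL/6J mice. Cells were cultured in 200 µL of medium on plastic coated at 1 µg/mL with antibodies to CD3, the signalling part of the T cell receptor complex, and to CD28, a costimulatory receptor. Cells were harvested after 6 h. In 3 samples the medium contained recombinant mouse CCL19, a chemokine that binds the receptor CCR7 on naive T cells, and in the other 3 it did not. The comparison asks how the chemokine alters the transcripts of T cells that are receiving an activating stimulus. The CCL19 libraries held 16978736, 26980697 and 21509499 counts assigned to genes, and the no-CCL19 libraries held 23816093, 27429898 and 18203667. Between 13790 and 14360 genes had at least 1 count in a library. Nothing in the sample descriptions says that the replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

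With CCL19, several transcripts of early T cell activation stood higher and several of the resting state lower, by less than 2-fold for all but 1 of the genes that DESeq2 called. edgeR and limma-voom called no gene, and the TCR activation and quiescence lists passed camera at its preset correlation but not with an estimated one (adjusted p = 0.678 for both). The mRNA of Il2ra, the high-affinity subunit of the interleukin-2 receptor, stood at 388 ± 52.6 CPM (counts scaled to library size by TMM, mean ± SD, n = 3) with CCL19 and 265 ± 42.0 CPM without it (1.47-fold). Il2, the growth factor that activated T cells secrete, stood at 44 ± 5 against 29.3 ± 5 CPM (1.5-fold). Cd69, a surface protein displayed within hours of stimulation, stood at 518 ± 57.2 against 381 ± 53.6 CPM (1.36-fold), and the transcription factor Myc at 921 ± 133 against 685 ± 104 CPM (1.34-fold). In the other direction, Klf2, a transcription factor that keeps T cells quiescent and recirculating, stood at 386 ± 25.9 against 576 ± 62.2 CPM (0.669-fold). For each of these 5 genes, all 3 libraries of one group lay on the same side of all 3 of the other. For Klf2 this was a condition of the rule that named it.

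How many genes passed a threshold depended on the test and its settings. edgeR's quasi-likelihood test called 0 genes higher and 0 lower at a Benjamini-Hochberg adjusted p under 0.05 among the 11666 tested. The lowest edgeR adjusted p was 0.0505, shared by 361 genes, and 3213 genes (27.5%) had an unadjusted p under 0.05, 1696 of them higher with CCL19 and 1517 lower. With no filter on low counts the edgeR test called 803 genes higher and 797 lower, and with a robust prior 267 and 262. limma-voom also called 0 genes, with a lowest adjusted p of 0.051 and 3235 genes at an unadjusted p under 0.05. DESeq2 called 630 genes higher and 538 lower at an adjusted p under 0.05. Its calls were small in size, with a median log2 fold change of 0.34 (1.26-fold) among the higher and -0.36 among the lower genes, and 1 gene, Tex15, which is among those named by the rule set in advance, changed by at least 2-fold. The groups did not overlap in 3474 tested genes (29.8%), where chance gives 10% for 3 against 3 libraries on average over splits. Genes are not independent, and another split of these libraries gave 2432 such genes. That split kept CCL19 replicates 1 and 2 together, so it still held part of the CCL19 contrast.

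The DESeq2 count rested on particular libraries. It dropped to 55 genes without CCL19 replicate 1, to 123 without CCL19 replicate 2 and to 105 without no-CCL19 replicate 1, each of them among the 1168. It stood at 1704 without CCL19 replicate 3, of which 1064 were shared with the full set. edgeR, with 0 calls in the full set, called 772 genes higher and 827 lower without CCL19 replicate 3, and 235 higher and 278 lower without no-CCL19 replicate 3. By chi-square per degree of freedom, the closest pair of libraries crossed the groups, with 5.32 between CCL19 replicate 3 and no-CCL19 replicate 3, against 12.2 and 17.4 between CCL19 replicate 3 and the others of its group. By Pearson's r of log2 CPM the closest pair lay within a group, with 0.9935 between no-CCL19 replicates 1 and 2 against 0.9928 for the pair that crossed. On the leading component of log2 CPM, which held 41.8% of the variance, CCL19 libraries scored 25.4, 11.4 and 1.69 and no-CCL19 libraries -24.7, -7.27 and -6.61 (exact permutation p = 0.1, 2-sided, the smallest that 3 against 3 allows).

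**Figure D1:**
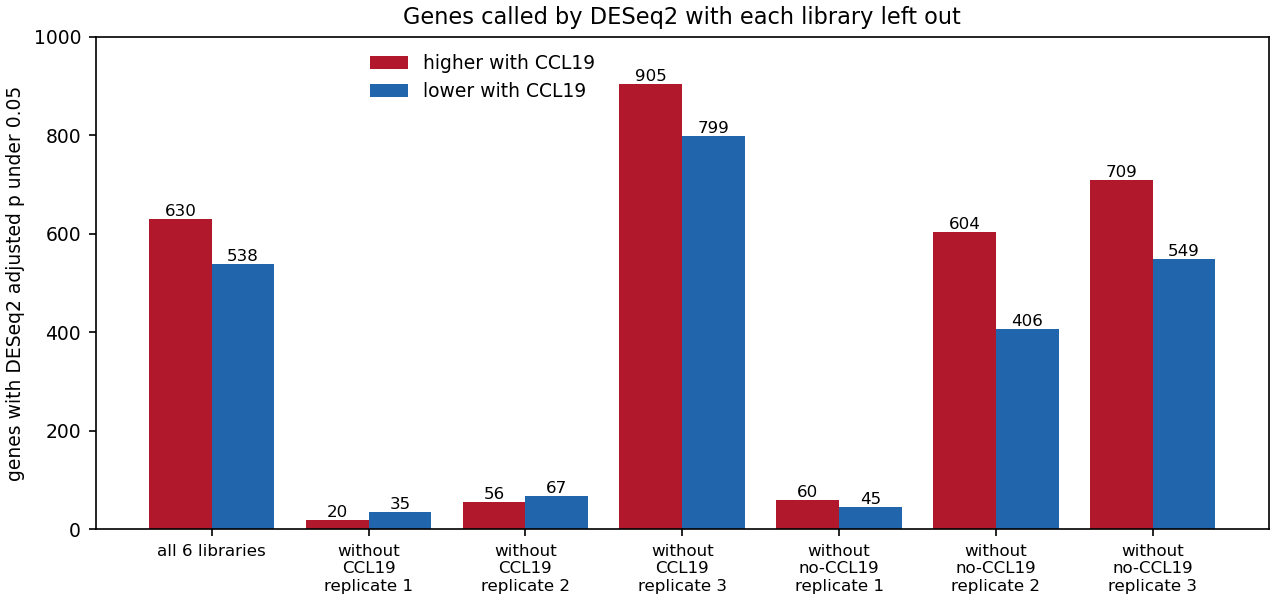
Bars give the number of genes (y axis) with a DESeq2 adjusted p under 0.05 that were higher (red) or lower (blue) with CCL19, for all 6 libraries and with each library left out (x axis). The full set gives 630 higher and 538 lower genes, and the counts range from 20 higher and 35 lower without CCL19 replicate 1 to 905 higher and 799 lower without CCL19 replicate 3.

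Of the genes named in advance, 5 given here were called by DESeq2 and none by edgeR. In mm10 coordinates, Il2ra (NCBI Gene 16184, chromosome 2, 11642792 to 11693194) had a log2 fold change of 0.55 ± 0.12 (SE; DESeq2 adjusted p = 0.00183, edgeR adjusted p = 0.0505). Il2 (NCBI Gene 16183, chromosome 3, 37120713 to 37125954) had 0.58 ± 0.12 (DESeq2 adjusted p = 0.00246, edgeR adjusted p = 0.0505) and Cd69 (NCBI Gene 12515, chromosome 6, 129267325 to 129275369) had 0.44 ± 0.11 (DESeq2 adjusted p = 0.00375, edgeR adjusted p = 0.0505). Myc (NCBI Gene 17869, chromosome 15, 61985341 to 61990361) had 0.43 ± 0.12 (DESeq2 adjusted p = 0.00948, edgeR adjusted p = 0.0606). Ccr7 (NCBI Gene 12775, chromosome 11, 99144199 to 99155077), which encodes the CCL19 receptor, stood at 358 ± 25.3 CPM with CCL19 and 445 ± 58.1 CPM without, a log2 fold change of -0.32 ± 0.10 (DESeq2 adjusted p = 0.0185, edgeR adjusted p = 0.0722). Without no-CCL19 replicate 1 the Ccr7 log2 fold change was -0.20 (edgeR adjusted p = 0.328). Cd4 (NCBI Gene 12504, chromosome 6, 124864693 to 124888209), the coreceptor used to define these cells, stood at 570 ± 25.6 against 634 ± 52.5 CPM. It did not pass in DESeq2 (adjusted p = 0.182) or in edgeR (adjusted p = 0.257).

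**Figure D2:**
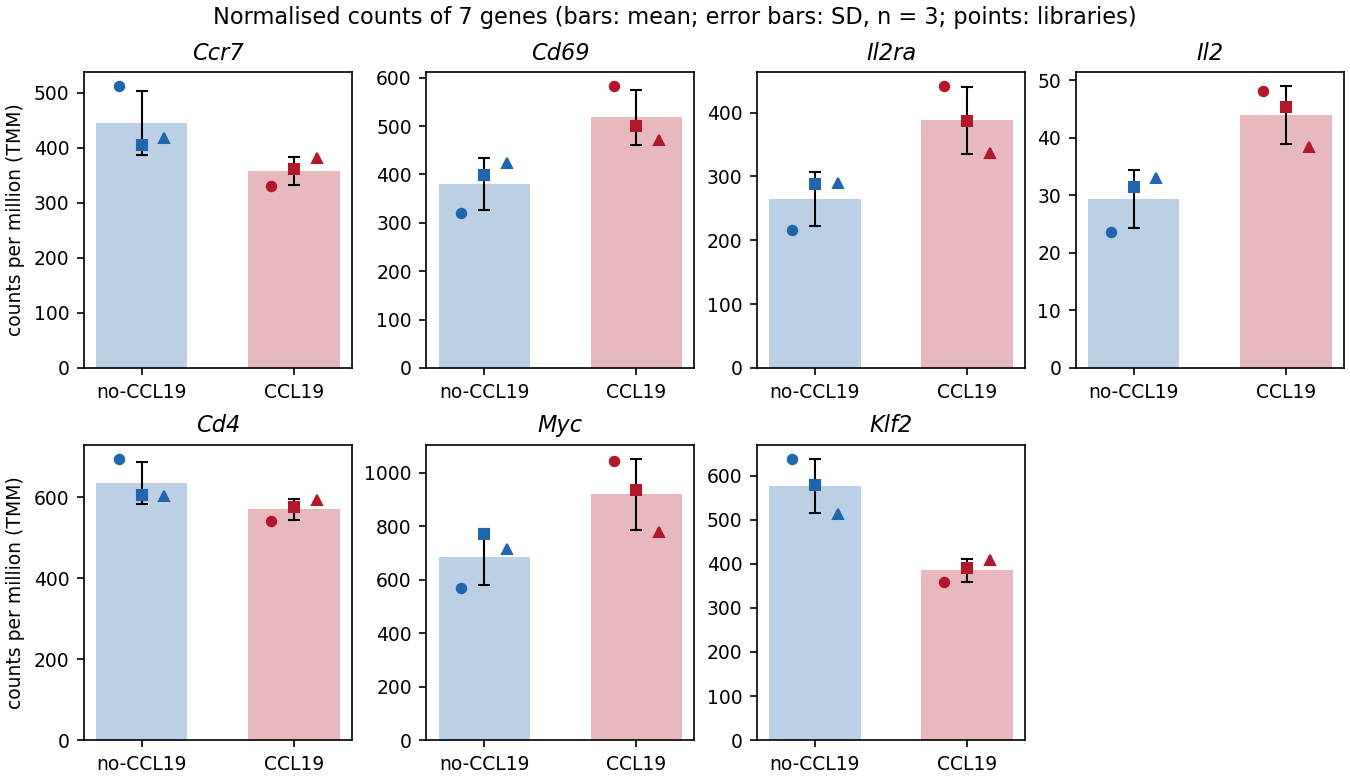
Bars give the mean CPM (y axis, scaled by TMM) of 7 genes without (blue) and with CCL19 (red), with error bars of 1 SD (n = 3) and a point per library (circle, square and triangle for replicates 1, 2 and 3). All CCL19 libraries lie above all no-CCL19 libraries for Cd69, Il2ra, Il2 and Myc and below them for Ccr7, Cd4 and Klf2.

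Since edgeR passed no gene, the 10 genes of smallest p in each direction among those that met the rule's conditions are given. They did not pass in edgeR (edgeR adjusted p = 0.0505 for each), and DESeq2 called them. The higher ones were Tex15, which acts in male germ cells, with 6.12 ± 1.64 CPM with CCL19 and 2.47 ± 0.509 CPM without (log2 fold change 1.31 ± 0.22), Usp2 (0.77), Insl6 (0.60), the endosomal tether Eea1 (0.56), the noncoding transcript AI504432 (0.50), the host transcript of the miR-17 cluster Mir17hg (0.47), the mitochondrial folate enzyme Mthfd2 (0.45), the mitochondrial ribosomal protein gene Mrps6 (0.44), Far1 (0.40) and Atad1 (0.37). Mrps6 overlaps Slc5a3 on the same strand over 29138 bp, so its counts are uncertain. The lower ones were Podnl1 (-0.82), the kinesin Kifc2 (-0.61), Klf2 (NCBI Gene 16598, chromosome 8, 72319062 to 72321654; -0.58 ± 0.09, DESeq2 adjusted p = 1.04e-06), Ptov1 (-0.56), the sphingosine-1-phosphate receptor S1pr4 (-0.55), Rfx1 (-0.51), Bcl9l (-0.50), Phldb1 (-0.50), Afap1 (-0.46) and the histone methyltransferase Kmt5c (-0.45). Over all tested genes the fold change ran with base composition. Spearman's rho between transcript GC content and log2 fold change was -0.317 across 11188 genes, which are not independent replicates. All the lower genes above except Afap1 (51.27%) lay in the highest of 10 GC classes (57.8% to 72.5%). The median log2 fold change of that class was -0.145, and Klf2 had 61.56% GC. Against a median of 49.7% over tested genes, Cd69 (35.91%), Il2 (39.42%) and Il2ra (44.38%) lay below and Myc (53.34%) above. DESeq2 with an offset for GC content and length called 661 genes higher and 328 lower, of which 423 and 239 were among its calls without the offset.

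Gene lists fixed in advance were tested with camera, which compares a list's members with all other tested genes at a preset correlation of 0.01 between members. Of 42 lists tested, 11 rose and 2 fell with CCL19 at an adjusted p under 0.05. With an estimated correlation none passed, with a lowest adjusted p of 0.678, and fry, which asks only whether a list's genes move one way on balance, passed none either, with a lowest adjusted p of 0.19. Another split of the same 6 libraries into 3 and 3 passed 16 lists, against 13 for the real split. That split kept CCL19 replicates 1 and 2 together, so it still held part of the CCL19 contrast. The list results below carry that limit, and edgeR called 0 members of any list when adjusted over all genes.

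The clearest list by camera was that of MYC targets and ribosome biogenesis, the nucleolar and growth genes that activated lymphocytes switch on before they divide. It rose with a median log2 fold change of 0.29 (camera adjusted p = 3.98e-23; adjusted p = 0.678 with an estimated correlation). All 65 members had a log2 fold change above 0, DESeq2 called 40 of them higher, and edgeR called 57 adjusted over the list alone. The chaperonin Hspd1 stood at 441 ± 42.7 CPM with CCL19 and 309 ± 42.6 CPM without. The pseudouridine synthase subunit Dkc1 stood at 273 ± 20.4 against 196 ± 30.8 CPM, the snoRNP protein Nop58 at 422 ± 37.6 against 306 ± 40.4 CPM, and the ribosome assembly gene Wdr75 at 163 ± 17.2 against 122 ± 13.4 CPM.

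The TCR activation list rose with a median log2 fold change of 0.28 (camera adjusted p = 9.8e-09; adjusted p = 0.678 with an estimated correlation). DESeq2 called 15 of its 42 tested members higher and none lower, and edgeR called 22 higher and 1 lower adjusted over the list alone. Besides Il2ra, these included the transferrin receptor Tfrc at 180 ± 20.1 against 130 ± 19.3 CPM, the cytokine regulator Bhlhe40 at 68.2 ± 8.15 against 48.2 ± 8.42 CPM, and Cd200 at 48.2 ± 3.19 against 35.4 ± 4.14 CPM. The library scores of this list overlapped between the groups, since CCL19 replicate 3 scored -0.03 and no-CCL19 replicate 2 scored 0.02, and without CCL19 replicate 1 the median was 0.18. The MAPK and calcium feedback list holds inhibitors of signalling and also early response genes such as Egr1, Fos and Nr4a1. Many of its members are on the TCR activation list too, so the 2 results are not independent. The feedback list rose with a median of 0.20 (camera adjusted p = 0.00765, and 0.685 with an estimated correlation). DESeq2 called 3 of its 35 members higher, the inhibitors Spred1 (0.39) and Spry1 (0.37) and the orphan nuclear receptor Nr4a2 (0.30), and 1 lower, the diacylglycerol kinase Dgka (-0.35), which limits Ras activation. The groups overlapped for Spry1 and Nr4a2, and without CCL19 replicate 1 the log2 fold change was 0.26 for Spred1 and 0.19 for Nr4a2. edgeR called none adjusted over the list alone. The list's call was lost without CCL19 replicate 1 (median 0.07, camera adjusted p = 0.289), without no-CCL19 replicate 1 (0.12, camera adjusted p = 0.132) and without no-CCL19 replicate 3 (0.15, camera adjusted p = 0.153), while without no-CCL19 replicate 2 the median was 0.31.

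The T cell cytokine list rose with a median log2 fold change of 0.35 (camera adjusted p = 4.82e-05; adjusted p = 0.678 with an estimated correlation). DESeq2 called 7 of 26 tested members higher and 1 lower, and edgeR called 9 and 1 adjusted over the list alone. Beside Il2 these were led by Lif at 34.8 ± 4.98 against 23.1 ± 3.30 CPM, the B cell help ligand Cd40lg at 358 ± 32.8 against 271 ± 27.5 CPM, and Tnfsf11, which encodes RANKL, at 120.0 ± 15 against 89.1 ± 10.9 CPM. The list of NF-kB targets shares Il2, Cd40lg, Lta, Tnf and Csf2 with the cytokine list, so its result is not independent of that list. It rose with a median of 0.17 (camera adjusted p = 5.61e-06, and 0.678 with an estimated correlation). DESeq2 called 9 of its 40 members higher and 1 lower, and edgeR 11 and 1 adjusted over the list alone. They included the chemokine Ccl3 at 21.9 ± 2.13 against 15.1 ± 2.13 CPM and lymphotoxin alpha, Lta, at 251 ± 21.3 against 191 ± 23.2 CPM. Without CCL19 replicate 1 the median of the NF-kB list was 0.11.

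The naive and quiescence list fell, with a median log2 fold change of -0.23 (camera adjusted p = 4.53e-08; adjusted p = 0.678 with an estimated correlation). DESeq2 called 17 of its 41 members lower and none higher, and edgeR called 20 lower and 0 higher adjusted over the list alone. Beside Klf2 and Ccr7 these included the antiproliferative factor Tob1 at 41.0 ± 4.68 against 56.9 ± 4.36 CPM, Arl4c at 112 ± 12.1 against 148 ± 10.5 CPM, and Klf3 at 158 ± 16.9 against 207 ± 18.0 CPM. The list of CCR7 and its signalling components fell with a median of -0.12 (camera adjusted p = 0.013; adjusted p = 0.684 with an estimated correlation). DESeq2 called 11 of its 40 members lower and 1 higher, and edgeR called 11 and 2 adjusted over the list alone. The lower members included Ccr7 itself, the beta-arrestins, which uncouple receptors, with Arrb1 at 76.7 ± 4.10 against 97.2 ± 10.1 CPM, the guanine nucleotide exchange factor Arhgef1 at 1654 ± 105 against 2126 ± 207 CPM, and the phosphoinositide 3-kinase genes Pik3cd (-0.33) and Pik3cg (-0.33). The 11 ranged from -0.38 to -0.25. With the offset for GC content and length the log2 fold change was -0.21 for Arhgef1 and -0.21 for Pik3cd. Without no-CCL19 replicate 1 the CCR7 signalling list had a median of -0.07 (camera adjusted p = 0.0555).

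Lists of protein folding and amino acid supply also rose. The heat shock list had a median log2 fold change of 0.18 (camera adjusted p = 9.43e-05; adjusted p = 0.678 with an estimated correlation), and DESeq2 called 8 of 20 members higher, as did edgeR adjusted over the list alone. The chaperones Hspa8, at 2224 ± 201 against 1684 ± 177 CPM, Hsp90aa1, at 452 ± 43.9 against 322 ± 51.4 CPM, and Hsph1, at 374 ± 42.7 against 275 ± 27.1 CPM, led it together with Hspd1. Chaperone genes have near-identical copies elsewhere in the genome, and how reads with several matches were counted is not given in the sources used here, so their counts are uncertain. The unfolded protein response list had a median of 0.14 (camera adjusted p = 0.00292; adjusted p = 0.678 with an estimated correlation), with 8 of 28 members called higher by DESeq2 and 9 by edgeR adjusted over the list alone. They were endoplasmic reticulum chaperones, with Hspa5 (BiP) at 1042 ± 71.5 against 792 ± 85 CPM, Hsp90b1 (0.34), Pdia6 (0.32) and Dnajb11 (0.27), and the list's median was 0.07 without no-CCL19 replicate 1. The list of ATF4 targets and amino acid genes had a median of 0.23 (camera adjusted p = 4.98e-05; adjusted p = 0.684 with an estimated correlation), with 11 of 35 members called higher and 2 lower by DESeq2, and 16 and 3 by edgeR adjusted over the list alone. Its members moved apart: the mitochondrial folate genes Mthfd2, at 112 ± 7.55 against 81.8 ± 9.05 CPM, and Mthfd1l (0.33) and the aminoacyl-tRNA synthetase Eprs (0.36) were higher, whereas Trib3, a stress-induced inhibitor of ATF4, was lower at 12.6 ± 1.85 against 18.8 ± 3.44 CPM.

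The type I interferon response list rose with the largest median of the lists that passed, 0.38 (camera adjusted p = 9.8e-09; adjusted p = 0.684 with an estimated correlation), yet almost none of its genes passed alone. All 50 tested members had a log2 fold change above 0, but DESeq2 called 1, the surface protein Ly6a, at 232 ± 32.1 against 172 ± 36.1 CPM (DESeq2 adjusted p = 0.0202), and edgeR called 0 adjusted over the list alone. Library scores overlapped widely, at -0.12, 0.56 and 0.22 with CCL19 and -0.77, -0.21 and 0.31 without (exact permutation p = 0.4, 2-sided), and without no-CCL19 replicate 1 the log2 fold change of Ly6a was 0.27. The list's median was 0.19 without no-CCL19 replicate 1, 0.22 without CCL19 replicate 2 and 0.65 without no-CCL19 replicate 3. The interferon gamma response list rose with a median of 0.20 (camera adjusted p = 0.00292; adjusted p = 0.685 with an estimated correlation). DESeq2 called 3 of 39 members higher, the checkpoint ligand Cd274 (PD-L1) at 621 ± 68.4 against 458 ± 79.2 CPM, the kinase Jak2 (0.30) and the guanylate-binding protein Gbp8 (0.34), and edgeR called 0 adjusted over the list alone. Without no-CCL19 replicate 1 the list's call was lost (median 0.06, camera adjusted p = 0.205) and the log2 fold change of Gbp8 was 0.20, and without no-CCL19 replicate 3 the median was 0.32.

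The mitochondrially encoded list rose with a median of 0.27 (camera adjusted p = 0.00765; adjusted p = 0.678 with an estimated correlation) over 7 tested genes, of which DESeq2 called ND1, at 1346 ± 193 against 1015 ± 173 CPM, and ND2, at 816 ± 99.1 against 624 ± 105 CPM. The groups overlapped for both genes. edgeR called 5 adjusted over the list alone. The call was lost without CCL19 replicate 3 (median 0.23, camera adjusted p = 0.0673), without no-CCL19 replicate 2 (median 0.18, camera adjusted p = 0.0881) and with the offset for GC content and length (median 0.15, camera adjusted p = 0.0772). Of the 13 mitochondrial genes listed, ATP6, ATP8, COX2, COX3 and ND4L had 0 counts in all 6 libraries and ND3 had 8 in total, beside 503819 for COX1. How reads with several matches were counted is not given in the sources used here, and copies of these genes in the nuclear genome could not be checked. The list's fold changes and the share that follows therefore rest almost wholly on the other genes. Counts from the mitochondrial genome made up 1.09% ± 0.131 of each library with CCL19 and 0.918% ± 0.121 without (exact permutation p = 0.2, 2-sided). Cytosolic ribosomal protein genes made up 4.44% ± 0.236 and 4.69% ± 0.192 (exact p = 0.3), and hemoglobin genes 0.00154% ± 4.47e-05 and 0.00152% ± 0.000346 (exact p = 0.9).

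**Figure D3:**
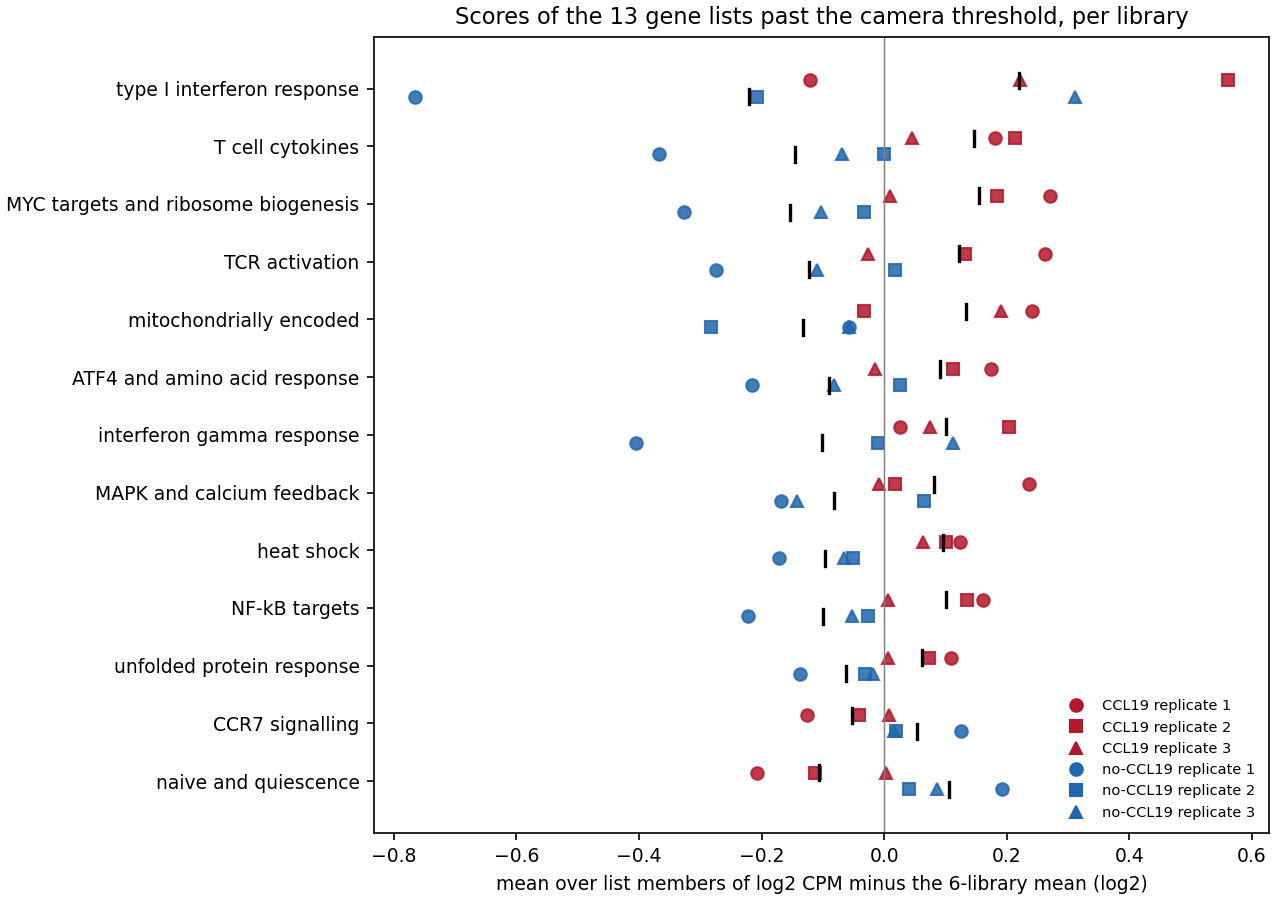
Points give each library's score (x axis, log2) for the 13 gene lists that passed camera (y axis), the mean over members of log2 CPM minus the mean of the 6 libraries, with CCL19 libraries in red, no-CCL19 libraries in blue and black ticks at group means. The scores of the MYC list run from 0.01 to 0.27 with CCL19 and from -0.33 to -0.03 without, and the type I interferon scores overlap, from -0.12 to 0.56 with CCL19 and from -0.77 to 0.31 without.

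The other 29 lists did not pass camera. Among helper subset lists, Th1 had a median log2 fold change of 0.19 (adjusted p = 0.0534), Tfh 0.11 (0.0934), Th17 0.11 (0.299), Th2 0.05 (0.838) and Treg -0.02 (0.686). Inhibitory receptors had 0.18 (0.0505), chemokine ligands 0.21 (0.0716), cytotoxic effectors 0.16 (0.111), cytokine receptors -0.08 (0.838), chemokine and migration receptors 0.02 (0.825) and integrins and adhesion -0.07 (0.554). Metabolic lists had medians of 0.13 for glycolysis (0.0544), 0.06 for oxidative phosphorylation (0.111), 0.07 for cholesterol synthesis (0.239), -0.02 for hypoxia (0.686) and 0.03 for oxidative stress (0.362). With the offset for GC content and length, glycolysis (median 0.19, camera adjusted p = 0.00498) and oxidative phosphorylation (median 0.08, camera adjusted p = 0.0417) passed. With an estimated correlation and no offset, their camera adjusted p was 0.684 and 0.685. The lists for G1 and S phase (0.08, 0.239), G2 and M phase (-0.06, 0.554), p53 targets (0.09, 0.113), the BCL2 family (0.05, 0.363), cytosolic ribosomal proteins (-0.04, 0.335) and T cell identity (-0.07, 0.111) did not pass either. Median and mean differed in sign for Treg, hypoxia, cytokine receptors, and macrophage and monocyte markers. The direction of the camera test differed from the median for Treg, hypoxia, chemokine and migration receptors, macrophage and monocyte, CD8 and neutrophil lists. Over these 29 lists edgeR called 52 memberships higher and 19 lower adjusted over the list alone. The histone list, with 4 tested members, and the stromal and endothelial list, with 2, were too small to test.

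Markers of other cell types that such a purification could carry over showed no list past the threshold. The single markers given here were chosen after their values were seen. B cell markers had a median log2 fold change of -0.17 (camera adjusted p = 0.239), with 11 of 16 members below 0, Cd79b at 3.91 ± 1.02 against 5.44 ± 1.07 CPM and Fcer2a at 14.5 ± 0.902 against 13.3 ± 3.26 CPM. CD8 T cell markers had 0.06 (0.855), with Cd8b1 at 13.3 ± 2.18 against 13 ± 0.231 CPM. NK cell markers had -0.04 (0.825), macrophage and monocyte markers 0.01 (0.825), dendritic cell markers 0.02 (0.686), neutrophil and granulocyte markers 0.07 (0.913), and erythroid and platelet markers 0.01 (0.531). Irf8, on the dendritic cell and TCR activation lists, stood at 165 ± 28.5 against 120 ± 22.0 CPM and Crtam, on the CD8 list, at 98.8 ± 3.47 against 76.9 ± 12 CPM; both are also expressed by activated T cells. Genes for the constant parts of the T cell receptor and of immunoglobulins were not found by symbol in the table and were not analysed here.

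The authors' deposited table of changed genes named 630 genes as higher and 538 as lower with CCL19. DESeq2, run here on the deposited counts at an adjusted p under 0.05, called the same genes in the same directions, 630 of 630 and 538 of 538. The table comes from these 6 libraries and is not independent evidence. The highest edgeR adjusted p among its tested genes was 0.12.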

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

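The GC and length offset, thinning, the fits without a pair of libraries and the alternatives to the DESeq2 counts were chosen after seeing the data. edgeR called 0 genes in the full set. Without a filter it called 803 higher and 797 lower, with a robust prior 267 and 262, and with each library left out between 0 and 772 higher and between 0 and 827 lower. Only the fits without CCL19 replicate 3 (772 and 827) and without no-CCL19 replicate 3 (235 and 278) gave calls. Without CCL19 replicate 3 and no-CCL19 replicate 1 together it called 468 and 439. It called 0 with DESeq2 size factors, with the stricter filter, and with the offset (lowest adjusted p 0.0918). A threshold of 0.01 and a 1.5-fold minimum on the same fit could only give 0. DESeq2 called 630 higher and 538 lower, and its overlap with the authors' list was 1168 against 0 for edgeR. The cause of these differences was not tested.

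The DESeq2 counts lay between 20 and 905 higher and between 35 and 799 lower with each library left out, and at 353 and 257 without the pair. They were 661 and 328 with the offset, 157 and 148 at 0.01, 19 and 19 at a 1.5-fold minimum, and 648 and 587 with filterByExpr first. With the replicate block DESeq2 called 103 and 75, with the offset and the replicate block 0 and 0 (lowest adjusted p 0.0655), and edgeR 0 and 0 (lowest adjusted p 0.162). Deviations of libraries with the same number correlated at -0.36, 0.21 and -0.063 over 8728 genes, and not every library correlated best with its own number. Deviations from a group mean of 3 constrain each other, so these values cannot show whether samples with the same number are paired. The labels do not say.

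camera passed 11 lists higher and 2 lower. It passed 0 and 0 with an estimated correlation, as did fry, and between 9 and 15 higher and between 1 and 2 lower with each library left out. It passed 14 and 2 without a filter, 13 and 2 with the replicate block, 12 and 2 with thinning, and 12 and 2 with the offset, where the mitochondrially encoded list no longer passed and glycolysis and oxidative phosphorylation did. Of 195 alternatives for the 13 lists, 159 kept the call and 36 lost it, and no median changed sign. With an estimated correlation and with fry the medians come from the main fit and could not change. The 13 lists had also passed in these same libraries, so the unchanged signs are not a sign of stability. Of 1052 alternatives for the 66 named genes, 714 stayed on the same side of the threshold, 338 passed it and 0 reversed. Most of these genes were chosen from these same libraries, DESeq2 called 64 of them, and the groups overlapped in only 5. The lack of reversals was thus largely fixed by the choice and is not a sign of stability. Of the 29 other lists, between 0 and 5 medians changed sign and between 0 and 5 lists passed in an alternative. Depth may limit the low-count genes, but its effect on single genes was not tested.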

Other observations

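The genes in this and the next paragraph were chosen after their values were seen, from lists that did not pass camera (some are also on lists that did), and DESeq2 called each of them while edgeR did not. Among regulators of cell death DESeq2 called 4 genes higher and 3 lower, with proapoptotic genes in both directions. Bcl2l1, which encodes the survival protein BCL-XL, stood at 116 ± 16.3 CPM with CCL19 and 83.6 ± 14 CPM without (log2 fold change 0.47 ± 0.12, DESeq2 adjusted p = 0.00837). The proapoptotic genes Bbc3, at 32 ± 1.94 against 45.4 ± 6.46 CPM (-0.51 ± 0.10, DESeq2 adjusted p = 0.00256), and Bad, at 5.6 ± 0.698 against 8.33 ± 0.825 CPM (-0.58 ± 0.15, DESeq2 adjusted p = 0.0264), were lower, whereas the proapoptotic genes Bid, at 51.3 ± 5.1 against 40.7 ± 3.62 CPM (0.33, DESeq2 adjusted p = 0.0298), and Fasl, at 51.9 ± 3.91 against 40.3 ± 4.08 CPM (0.37, DESeq2 adjusted p = 0.0161), were higher. Among inhibitory ligands and receptors, Pdcd1lg2 (PD-L2) stood at 39 ± 2.8 against 27.4 ± 3.96 CPM and Btla at 161 ± 14.5 against 123 ± 10.4 CPM. Among glucose and lactate genes, the hexokinase Hk2 stood at 70.6 ± 10.7 against 46.9 ± 7.84 CPM and the lactate transporter Slc16a1 at 184 ± 16.1 against 140.4 ± 15.3 CPM.

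Genes of adhesion and trafficking also moved in both directions. The integrin subunit Itgav stood at 114 ± 15 CPM with CCL19 and 85.6 ± 13.1 CPM without, and Jaml, an adhesion protein, at 10.7 ± 1.73 against 6.4 ± 2.1 CPM. The integrin subunit Itgb7, at 213 ± 20.2 against 271 ± 22.3 CPM, the selectin ligand Selplg, at 296 ± 26.6 against 385 ± 39.7 CPM, and the egress receptor S1pr1, at 406 ± 59.1 against 521 ± 71.7 CPM, were lower. Among cytokine receptors DESeq2 called 3 higher and 3 lower. Il15ra stood at 33.1 ± 3.29 against 21.4 ± 6.09 CPM, whereas Il6ra stood at 204 ± 11.5 against 258 ± 28.2 CPM, with Tgfbr3 (-0.33) and Il17ra (-0.26) also lower. Among cell cycle entry genes, Ccnd2 stood at 1437 ± 195 against 1069 ± 171 CPM and Cdk6 at 41.9 ± 3.85 against 30.8 ± 4.99 CPM, whereas Ccnd3 stood at 106 ± 8.28 against 130.5 ± 13.2 CPM.

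Of the tests below, those of the splits, of depth, of GC content against the activation lists, of the interferon spread and of the GC slopes were chosen after the result was seen. The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Each of the other splits has more CCL19 libraries on one side than on the other. It thus still carries part of any CCL19 effect, and its counts are not chance values alone. DESeq2 called 1168 genes in the real split and at most 206 in the others, so 1 split gave a count as large, itself. Unadjusted p under 0.05 numbered 3213 in the real split and at most 1728 in the others, again 1 split. edgeR called 0 genes in all 10. For camera, 3 splits passed as many lists as the real one or more, with 13 in the real split and up to 16 in the others.

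The growth and activation lists stood higher and the quiescence list lower with CCL19, a net difference of 0.505 on the log2 scale. It is the mean of the medians of the MYC, TCR activation, T cell cytokine and NF-kB lists minus the quiescence median. The tables argue against GC content and transcript length as the whole cause, since the difference was 0.535 with the offset. With every library thinned to the smallest total the difference was 0.515. Thinning keeps each gene's expected share of the counts, so this value cannot decide whether depth played a part. Library totals overlapped between the groups (exact permutation p = 0.7, 2-sided). A single library stays open, because leaving out 1 library took the difference to between 0.365 and 0.655. Samples that reached different degrees of activation for reasons other than CCL19 cannot be told apart from an effect of CCL19. The groups did not overlap on this axis (highest no-CCL19 score minus lowest CCL19 score -0.0565). However, its lists had passed camera in these same libraries, so this separation is partly built in, and the scores of TCR activation alone overlapped. With 3 libraries in a group no value can exclude different degrees of activation. An effect of CCL19 stays open as the explanation that the design names.

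The interferon list was higher with CCL19 by a median of 0.38, and differences between libraries of the same group may account for it. The widest range within a group was 2.45 times the difference between group means, and library scores overlapped. The median was 0.188 without no-CCL19 replicate 1, 0.215 without CCL19 replicate 2 and 0.648 without no-CCL19 replicate 3. Its size thus depended on more than a single library. A response to CCL19 was not excluded.

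Genes with GC-rich transcripts were lower with CCL19, with Spearman's rho of -0.317 across genes and medians from 0.119 in the lowest GC class to -0.145 in the highest. Genes are not independent replicates. The tables argue against the composition of the fixed lists as the cause, since rho was -0.33 over genes in no list. A bias of single libraries by GC content that is unrelated to the group may account for the trend. Log2 slopes per 10 points of GC were -0.057, -0.0217 and -0.0973 with CCL19 and 0.0924, 0.124 and -0.0402 without. The groups overlapped only through no-CCL19 replicate 3 (lowest no-CCL19 minus highest CCL19 slope -0.0185). No value in 6 libraries could exclude such a bias, so the slopes cannot decide this. Genes that the authors named as higher had a median GC content of 45.8% and those named as lower 55.9%, against 49.7% over tested genes. A response to CCL19 that differs with GC content stays open and was not tested.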
